A study of Drosophila melanogaster with 4 samples.

How the data were processed

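Su(Hw) was immunoprecipitated from formaldehyde-fixed wild-type Oregon-R embryos of Drosophila melanogaster at 14 to 16 h, per the labels' protocols. The 4 samples fall into 2 groups, 2 ChIP samples and 2 input samples, each input serving the ChIP list of the same number, per the labels. The inputs have no list of their own and entered the values only through the authors' calling. Reads were processed with Bowtie 0.12.7, per the submitters' processing notes. The region caller, its threshold and the scaling of ChIP to input are not given in the sources used here. Any of these could change which weak regions are listed.

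The 3 deposited region lists give chromosome, start, end and a score, with positions counted from 1 in FlyBase release 5, per the file headers. Regions were called per replicate in a pair of lists, and the remaining list is the series' combined list. The score is the authors' deposited log2 enrichment of a region, with a zero point set by the authors. Its scale is not stated in the headers and was settled from the values: 44 pairs of distinct scores in the combined list, 93 in replicate 1 and 73 in replicate 2 differed by exactly 1 (tolerance 1e-11), and 0 in each list by the natural or decimal logarithm of the number 2. The zero point is not given in the sources used here, so no score is given as a fold over input. Because each list may have been normalized separately, a score difference between replicates is described and not tested. Regions marked as depleted by the authors (5 in the combined list, 1 in replicate 1 and 0 in replicate 2) were left out of the comparisons. Depth is unknown, so no interval that needs read counts is given, and binomial and Poisson intervals cover counting of regions only.

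Regions were called shared when they overlapped by at least 1 bp. The null for sharing was 1000 circular shifts of one list along each sequence. Scores of shared regions were compared by Pearson's and Spearman's correlation with 100000 permutations. Densities used the sequence lengths per the file headers, with exact Poisson intervals and chi-square tests against length. These lengths were not corrected for assembly gaps or for sequence where reads cannot be placed. The 1 Mb windows left out the incomplete last window of each arm, and centromere-proximal ends follow the standard orientation of the arms. Scores per arm were compared by 10000 permutations with Benjamini-Hochberg adjustment. The arithmetic was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. Overlaps computed in Python were checked with bedtools 2.31.1, which gave the same 4386, 4385 and 4328 regions. The overlap and score-difference steps were tested on simulated data. Of 4999 simulated regions 79.6% were kept and 79.7% found shared. Of 200 sites changed by 1.5, 196 were recovered, with 0 called lower. The change of 1.5 was set above the threshold of 1 for a score difference, so high recovery was built in. These counts check only that the steps run as intended. Error rates on the real pairs, whose differences had an SD of 0.39, were not measured.

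Before the data were examined, the named sites were fixed as the 15 best-scoring combined regions found in both replicates, and the 3 best-scoring regions of each replicate alone, with ties going to the lower coordinate. Alternatives fixed then were reciprocal 50% overlap, midpoints within 250 bp, the better-scoring 50% or top 1000 of each list, and the large arms with chromosome 4 alone. Also fixed then were uniform placement as null, pairs with 1 partner each, each replicate's list for the densities, and the listed span as length. Alternatives added after seeing the data were the depleted regions, the 1 Mb window tests and pairs with near midpoints. Also added then were the large arms with chromosome 4 for the combined list, and all settings of the score difference between replicates. Results on annotation classes, the Su(Hw) motif and gene lists were planned but not run, because the gene table at hand follows Release 6 of the genome and no sequence of release 5 was used here. Positions were not converted between builds.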

Results

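Binding of Su(Hw), a zinc-finger protein that binds the insulator of the gypsy retrotransposon, was mapped by ChIP-seq in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. The series held 4 samples, made of 2 ChIP samples with 1 antibody and 2 input DNA samples. Each ChIP sample was represented by a list of regions called against the input of the same number, and a combined list covered both replicates. The 3 lists gave each region's position in FlyBase release 5 and an enrichment score of the authors on a log2 scale. No read counts were used here, so the depth behind each score is unknown. The labels do not say that the ChIP samples came from separate embryo collections, so differences between them may be technical.

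Su(Hw) regions were found on every large chromosome arm. The combined list held 5892 enriched regions, against 4999 in replicate 1 and 4662 in replicate 2. Median widths were 2231 bp in the combined list, 2253 bp in replicate 1 and 2269 bp in replicate 2. The combined regions covered 14239 kb, or 8.44% of the build. That build length includes Uextra (29.0 Mb), 2LHet (0.37 Mb) and YHet (0.35 Mb), on which no list held an enriched region. The median score was 0.92 in the combined list, 1.14 in replicate 1 and 1.41 in replicate 2, and each list may have been normalized separately.

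The strongest region found in both replicates lay on U, the unplaced scaffolds, at 4251754 to 4254200, with a combined score of 5.56. Its score was 4.63 in replicate 1 and 6.24 in replicate 2. The next lay on 3R at 27282298 to 27286666, with a combined score of 4.77 and scores of 4.91 and 4.98 in replicates 1 and 2. A region of the heterochromatic scaffold 2RHet at 368436 to 372944 followed with 4.74, from 3.99 in replicate 1 and 5.64 in replicate 2. Among the 15 strongest regions, 6 lay on 3L, 4 on 3R, 2 on 2L, 2 on U and 1 on 2RHet. None lay on X, 2R or chromosome 4. The 6 on 3L were at 21041424 to 21044092 (combined score 4.60), 2242226 to 2246016 (4.37), 22447338 to 22451028 (4.24), 4838910 to 4842552 (4.17), 22886378 to 22891544 (4.16) and 11514490 to 11517770 (4.15). The other regions on 3R were at 10132408 to 10135268 (combined score 4.31), 19426278 to 19429076 (4.16) and 1973764 to 1977132 (4.09). Those on 2L were at 488882 to 491376 (combined score 4.19) and 3130496 to 3133258 (4.14), and the other region on U was at 9904636 to 9907158 (4.28). Replicate scores lay within 0.5 of each other at 13 of the 15, and the exceptions were the first region on U and the one on 2RHet. Genes at these positions were not analysed here, because no annotation of release 5 was used.

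The widest region of the combined list spanned 13237 bp on 2L, from 20281938 to 20295174. Its score was 3.14. Each replicate listed this stretch as 2 separate regions, with scores of 3.05 and 3.35 in replicate 1 and 2.65 and 3.15 in replicate 2. Further wide regions lay on 3L at 9458204 to 9468684 (10481 bp), on X at 14847394 to 14857652 (10259 bp) and on 3R at 18163280 to 18173476 (10197 bp), and each of these too covered 2 or 3 regions of each replicate list. The next widest, on 3L at 8241294 to 8250270 (8977 bp), was 1 region in each replicate list. These wide regions were chosen after their values were seen.

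The first comparison asked how far the replicates listed the same regions. Of the replicate 1 regions, 4386 of 4999 (87.7%) overlapped a replicate 2 region by at least 1 bp. Conversely, 4385 of 4662 replicate 2 regions (94.1%) had a partner in replicate 1. Shared regions were the stronger ones: with each list cut into 10 equal parts by score, the lowest part of replicate 1 was shared at 56.0% (95% exact interval 51.5 to 60.4) and part 3 at 71.0%, while parts 5 to 10 were shared at 99.8% to 100%. The lowest part of replicate 2 was shared at 74.3% (70.1 to 78.2). Random circular shifts of the replicate 2 list along each sequence gave a mean of 18.1% of replicate 1 regions shared and at most 31.0% in 1000 shifts (one-sided permutation p = 0.001, the smallest they can give).

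**Figure D1:**
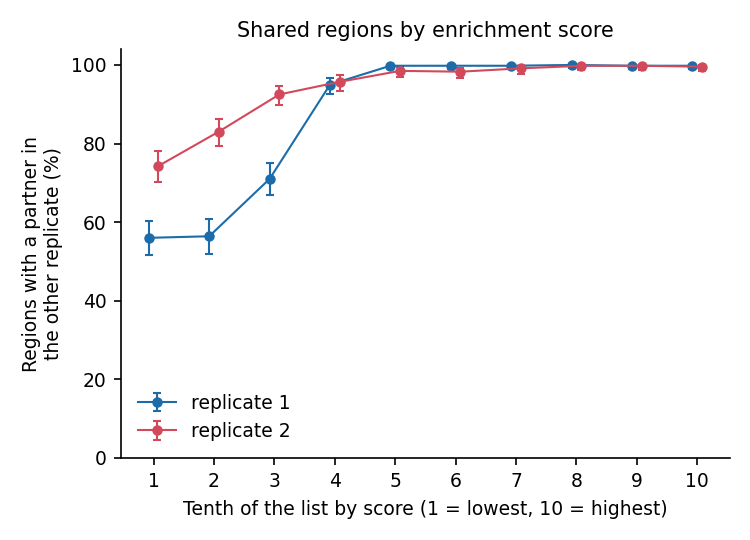
Percentage of regions of each replicate list that overlapped a region of the other replicate, for 10 equal parts of the list from the lowest to the highest score, with 95% exact binomial intervals as bars. In replicate 1 the lowest part stood at 56.0%, and in replicate 2 at 74.3%.

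Replicate 1 alone listed 613 regions (12.3%) and replicate 2 alone 277 (5.94%). Their median scores were 0.41 in replicate 1 and 0.43 in replicate 2, against 1.34 and 1.5 for the shared regions of the same list. The strongest regions of replicate 1 alone lay on 2RHet at 2182829 to 2184297 (score 2.73), on 3L at 24416302 to 24417642 (2.47) and on U at 4230705 to 4232218 (1.63), and none of these 3 was in the combined list. The strongest of replicate 2 alone lay on U at 9550959 to 9552320 (score 5.87), on U at 6127977 to 6129354 (3.74) and on 3L at 17399153 to 17401507 (2.65). Among these 3, the second was absent from the combined list, and the others had combined scores of 4.04 and 1.76. Scores above 1 were given to 4 of the regions of replicate 1 alone and to 26 of those of replicate 2 alone.

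Scores of regions shared by the replicates were correlated. Across 4386 replicate 1 regions and their best-scoring partners, Pearson's r was 0.896 and Spearman's rho 0.890 (permutation p = 1e-05 for both, the smallest 100000 permutations can give). These are correlations across regions of a pair of libraries, and regions are not independent replicates. Of 3963 pairs with 1 partner in each list and midpoints within 250 bp, 173 (4.37%) scored over 1 higher in replicate 2 and 0 scored over 1 higher in replicate 1. The median difference over all pairs was 0.02 (SD 0.39), and the lists may have been normalized separately. At 3L 3367473 to 3369362 the score was 0.24 in replicate 1 and 2.75 in replicate 2, and at 2R 3340704 to 3342640 it was 0.38 and 2.84. In the opposite direction, the furthest region lay on 2R at 16386753 to 16388945, with 1.02 in replicate 1 and 0.33 in replicate 2. This pairing and these sites were chosen after the values were seen.

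**Figure D2:**
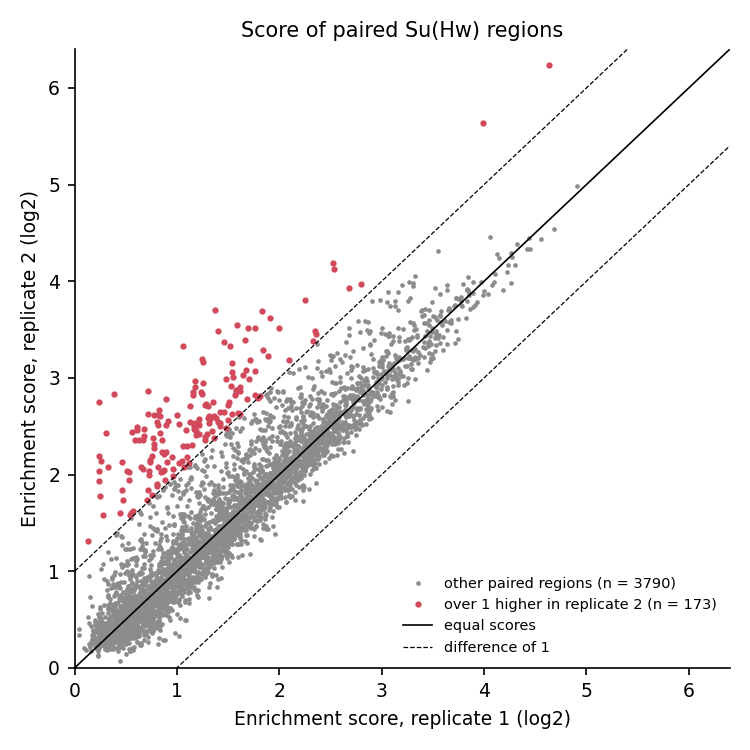
Log2 enrichment score of 3963 paired regions, with replicate 1 on the horizontal axis and replicate 2 on the vertical axis. Each point is a region, the solid line marks equal scores, the dashed lines a difference of 1, and the 173 red points lie over 1 higher in replicate 2.

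The combined list held regions of all kinds of support. Of its 5892 regions, 4328 (73.5%, 95% exact interval 72.3 to 74.6) overlapped a region in both replicates. A further 559 (9.49%) overlapped replicate 1 alone, 243 (4.12%) replicate 2 alone and 762 (12.9%) neither. Regions found in both had a median score of 1.41, against 0.26 for those with replicate 1 alone, 0.27 with replicate 2 alone and 0.31 with neither. On U, 17 of 41 combined regions were found in both replicates and 20 in neither, whereas on XHet, the heterochromatic scaffold of X, all 10 were found in both. When only the better-scoring 50% of the combined list was used, 98.5% were found in both replicates, and with midpoints within 250 bp the share over the whole list was 64.6%.

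In the combined list, Su(Hw) regions were densest on X among the large arms. The combined list gave 55.0 regions per Mb on X (95% exact Poisson interval 52.0 to 58.2), 51.7 on 3R (49.0 to 54.4), 48.5 on 2R (45.6 to 51.6), 44.2 on 2L (41.5 to 47.0) and 43.5 on 3L (40.9 to 46.2). X and 3R lay closer in the replicate lists, at 45.5 and 44.6 per Mb in replicate 1 and 42.6 and 40.8 in replicate 2. They were not tested against each other. On X, 184 of 1234 combined regions (14.9%) were found in neither replicate, against 10.4% to 13.3% on the other large arms. Chromosome 4 held 13 combined regions, or 9.62 per Mb (5.12 to 16.4). Among the scaffolds, U had 4.08 regions per Mb, 2RHet 4.56, 3LHet 7.43 and 3RHet 3.18, whereas XHet had 49.0 (23.5 to 90.1). All 10 XHet regions lay in 1 stretch of 59.5 kb at near-even spacing. Its density and interval therefore do not describe independently placed regions. The counts on the 6 arms differed from those set by arm length (chi-square 89.6, p = 8.2e-18), also without chromosome 4 (chi-square 47.0, p = 1.5e-09). X exceeded 2L, 2R, 3L and 3R together 1.17-fold (95% exact interval 1.1 to 1.24; chi-square 23.5, p = 1.3e-06). This contrast was not named in the plan, which held the test of the arm counts against length. The other large arms also differed, from 43.5 to 51.7 per Mb, so no test here separates X from spread between arms. The chi-square test takes regions as independently placed, so whole 1 Mb windows were also compared, in a test added after the data were seen. X windows held 55.2 ± 12.2 combined regions (SD, n = 22) against 47.3 ± 13 on the autosomal arms (n = 95; two-sided permutation p = 0.011). For the same windows the permutation p was 0.044 in the replicate 2 list and 0.074 in the replicate 1 list, so the difference did not pass 0.05 in replicate 1. Without the 2 complete windows nearest each centromere, the permutation p was 0.0033 in the combined list, 0.022 in replicate 2 and 0.049, close to the threshold, in replicate 1.

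**Figure D3:**
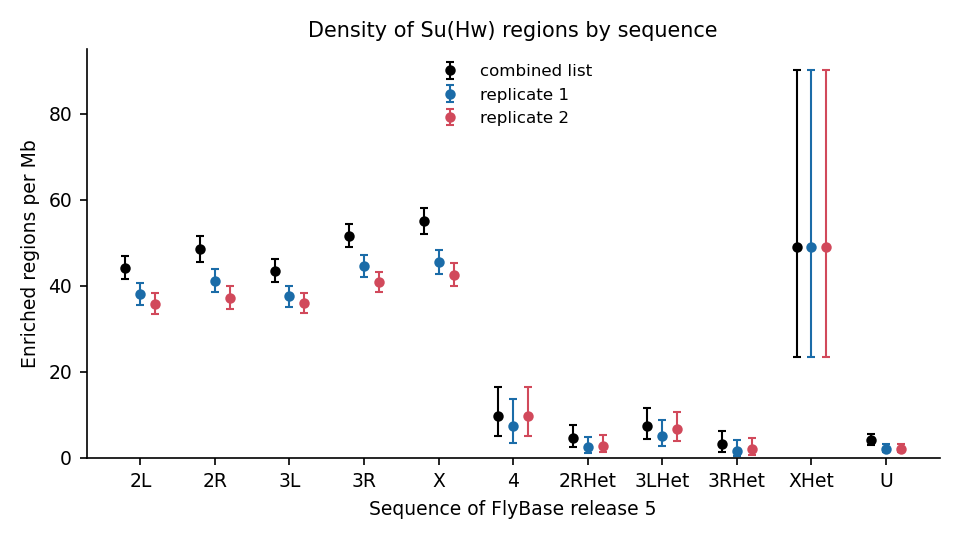
Enriched Su(Hw) regions per Mb on each sequence of FlyBase release 5 with a listed region, for the combined list and both replicate lists. Bars are 95% exact Poisson intervals. X stood at 55.0 per Mb and chromosome 4 at 9.62 per Mb in the combined list.

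Along the arms, the ends next to the centromere held fewer listed Su(Hw) regions per Mb than the rest. In the 2 Mb nearest the centromere, 2L had 8.0 combined regions per Mb against 47.6 on the rest of the arm, 2R had 9.5 against 52.6 and 3L had 14.5 against 46.0. On 3R the values were 33.5 and 53.1, and on X 37.5 and 56.8. The 2 Mb at the opposite ends held 41.0 regions per Mb on 2L, 48.5 on 2R, 43.0 on 3L, 56.0 on 3R and 60 on X. The densest 1 Mb window was X from 18 to 19 Mb, with 78 combined regions, 60 in replicate 1 and 58 in replicate 2. The window with the next highest count, X from 1 to 2 Mb, had 76 combined regions but 54 in replicate 1 and 39 in replicate 2. No test was run on these ends or windows, which were chosen after their values were seen. How much of their sequence reads could be placed on was not measured, so fewer listed regions need not mean less binding.

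**Figure D4:**
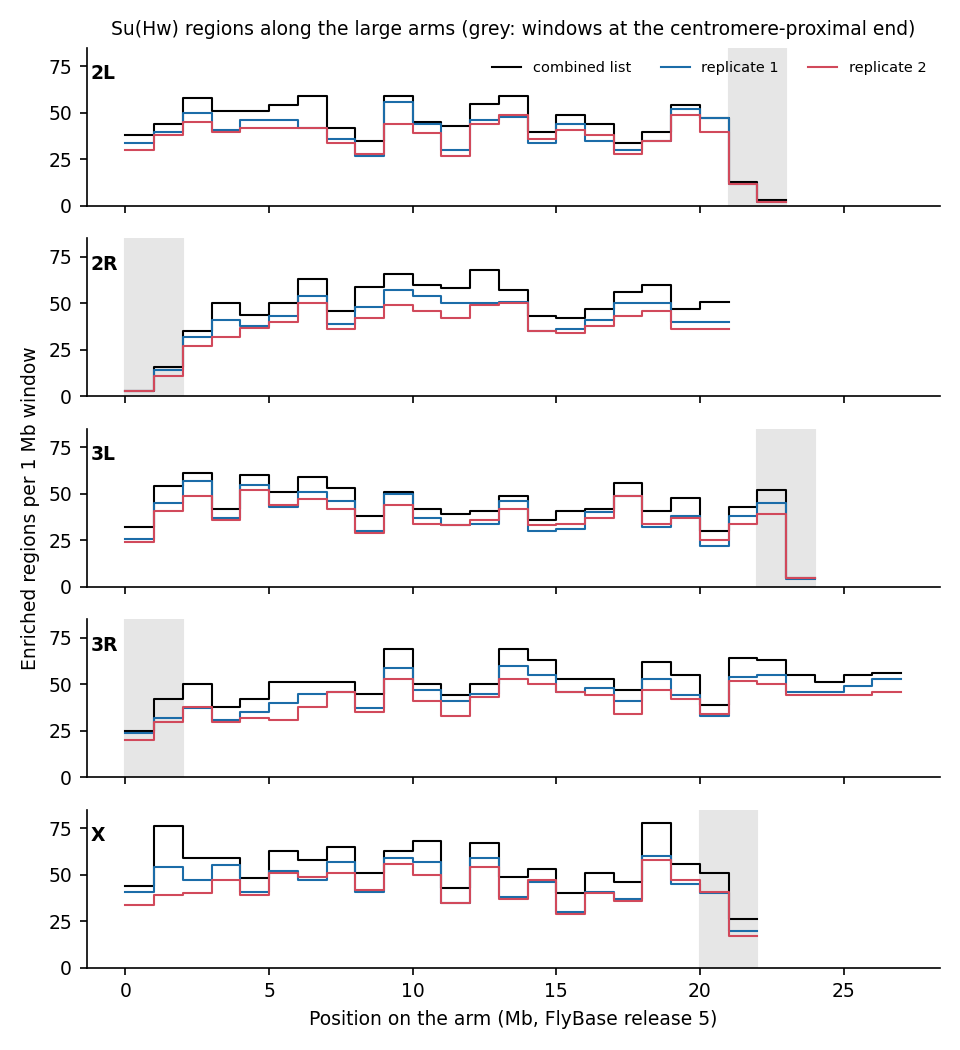
Enriched Su(Hw) regions per 1 Mb window along 2L, 2R, 3L, 3R and X, for the combined list and both replicate lists, with position in Mb of FlyBase release 5. Grey marks windows at the centromere-proximal end, where 2L fell to 3 combined regions in its last complete window.

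The 13 regions of chromosome 4 had a median score of 1.85 in the combined list, against 0.92 on the other arms (permutation p = 0.0275, Benjamini-Hochberg adjusted p = 0.165 over 6 arms). No arm's median score passed the adjusted threshold in the combined list or in either replicate list. The strongest regions on chromosome 4 were at 431742 to 437882, with 3.52 in the combined list, 4.33 in replicate 1 and 3.35 in replicate 2, and at 1132508 to 1135222, with 3.38, 3.21 and 3.50.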

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

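The 5 regions below were picked out because they lay outside the enriched regions that the comparisons used; all tests of the patterns weighed here were chosen after the pattern was seen, and the tests by neighbouring sites and by the input had their bounds written before their values were computed. The rule that the whole interval must clear a bound was applied after these values were seen; both values alone lay on the side that argues against the explanation, below 0.1 for neighbouring sites and below 1.2 for the input.

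The combined list marked 5 regions as depleted, on 2R at 5801600 to 5803290 (score -0.04), 3L at 18638592 to 18640176 (-0.03), U at 262362 to 263996 (-0.02), 3RHet at 2377464 to 2379314 (-0.02) and 3LHet at 1396046 to 1397790 (-0.14). Replicate 1 marked 1, on 3RHet at 2377485 to 2379209, and replicate 2 marked 0.

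The 173 sites scoring over 1 higher in replicate 2, against 0 in replicate 1, lay at 27 of 704 pairs on 2L, 36 of 662 on 2R, 35 of 730 on 3L, 40 of 991 on 3R, 28 of 823 on X, 2 of 7 on chromosome 4, 2 of 6 on 2RHet, 2 of 17 on U and 1 of 11 on 3LHet. The median difference of 0.0156 over all pairs depends on the zero point of each list, but centring on it removes any uniform rise of replicate 2 scores. With differences so centred, 168 sites were still over 1 higher in replicate 2 and 0 in replicate 1. A shift equal at all sites therefore does not set these sites apart from the other pairs. The median was small beside the limit of 1, so centring could change few of the counts. Because the zero points are not known, whether the whole replicate 2 library rose uniformly cannot be told from these scores. A stronger enrichment of that library that changes scores unevenly was not tested and stays open. Differences at adjacent sites correlated weakly (r = 0.0957, interval 0.0645 to 0.127, permutation p = 0.001, the smallest 1000 permutations can give), which lay below the 0.3 a regional difference was taken to need but not clear of 0.1, so a regional part stays open. A higher input of replicate 1 at these sites also stays open. The denominators of their score ratios per kb were 1.19 times those of score-matched sites, with an interval of 0.929 to 1.36. This lay below the 1.5 a higher input was taken to need but not clear of 1.2. The ratios are known only up to a rational factor per list, so their denominators need not equal input read counts. No biological explanation was tested, because both ChIP samples belong to 1 group.

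The 890 regions listed in 1 replicate alone were in the combined list in 807 cases (90.7%), and their median scores lay in the lowest 25% of their lists. Of all regions, 99.0% of replicate 1 and 99.3% of replicate 2 were in the combined list, above the 91.8% and 88.1% of those listed in replicate 1 or 2 alone. Because the combined list covers the same libraries, its share does not decide whether a threshold of the region calling sets these regions apart, and that stays open. Scores above 1 were held by 4 regions of replicate 1 alone and 26 of replicate 2 alone, and the threshold was not tested on these strong regions. No biological explanation was tested.

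The combined list also held 30 regions with scores above 1 that neither replicate listed, of which 19 lay on U or heterochromatic scaffolds and 22 were narrower than 1100 bp. The highest, at 3.15, was shared by 3 regions, on 3LHet at 261008 to 262148 and on U at 3030896 to 3031898 and 9260372 to 9261376. Every score of the 3 lists matched log2 of a ratio of whole numbers with a denominator up to 20000 plus a constant per list, known only up to a rational factor (tolerance 1e-11), against 1.66% to 2.79% of scores after random jitter. The median denominator of that ratio in lowest terms was 2 in these regions against 321 in regions found in both replicates, so scores set by few reads are a candidate explanation. Reads shared between repeated copies were not tested, and no biological explanation was tested.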

How the results depend on the processing

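The alternatives of the score difference, the window tests and the depleted regions were chosen after seeing the data. So were the near-midpoint pairs and, for the combined list, the large arms with chromosome 4. The share of replicate 1 regions found in replicate 2 stayed above its null under all 7 alternatives. It ran from 76.4% (top 1000 of each list) to 87.8% (large arms with chromosome 4). The correlation of scores stayed positive, with rho from 0.756 (better-scoring 50%) to 0.905 (near midpoints). The X to autosome ratio stayed above 1 and past its threshold in the combined list, from 1.14 to 1.19, and by chi-square in the replicate 1 list (1.12) and the replicate 2 list (1.13). In the replicate 1 list the permutation over windows gave p = 0.074, or 0.049 without the 2 complete windows nearest each centromere. The share of combined regions found in both replicates moved to 64.6% with midpoints within 250 bp and to 98.5% in the better-scoring 50%. Found in the 1 remaining replicate, it ranged from 77.6% to 82.9% by its construction. All listed regions were at least 1001 bp wide, so those with midpoints within 250 bp always overlap. The share under that rule could thus only fall. The combined list covers the same libraries, so the rise in its better-scoring 50% is not independent of the replicate lists. What else sets that rise was not tested. At a threshold of 0.5, 475 sites scored higher in replicate 2 and 15 in replicate 1. In the better-scoring 50% the densities of the 6 arms fell to 5.18 to 27.8 per Mb, since fewer regions were counted. Planned results on annotation classes, the motif and gene lists were not run. No paired analysis was possible because the inputs that share numbers with the ChIP samples have no lists. The unknown depth limits what can be said of weak regions.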

Other observations

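All tests and sites in this part were chosen after the results were seen, and the bound of the spacing test was written before its value was computed.

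On XHet, the 10 combined regions lay between 89438 and 148888, a span of 59.5 kb, and all 10 were found in both replicates. Neighbouring midpoints were 6.37 ± 0.796 kb apart (SD over 9 distances), from 5.31 to 7.62 kb. Widths ran from 2093 to 3355 bp and combined scores from 0.68 to 1.16. The sequence under these regions was not analysed here.

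On the large arms the median gap between neighbouring combined regions was 9.99 kb, and 72 gaps exceeded 100 kb. The longest gap was 806 kb on 2L, from 22054197 to 22859733, and the longest on 2R was 567 kb, from 1011801 to 1578431. The densest 100 kb windows were 2R 17400001 to 17500000 with 14 regions, of which 7 were found in both replicates, and 5 windows with 13 regions each. Of these, 2L 13600001 to 13700000 and 3L 13500001 to 13600000 each had 12 regions found in both.

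Sparse centromere-proximal ends might account for the uneven spacing of regions along the arms. The variance-to-mean ratio of regions per 100 kb was 1.57 over whole arms, against at most 1.19 in 1000 uniform placements of the same regions. Without the 2 Mb nearest each centromere it was 1.37, against at most 1.15. Uneven spacing was thus left after the ends were removed, which argues against the ends as its whole cause. What else sets the spacing was not tested.

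At the nearest paired site within 20 kb of 109 sites that scored over 1 higher in replicate 2, the median difference was 0.10 (bootstrap interval 0.02 to 0.26), and 8 of the 109 neighbours were themselves over 1 higher. Over all pairs the median difference was 0.0156, and 173 of 3963 (4.37%) were over 1 higher. The 2 were not tested against each other. The neighbour measure was added after the correlation of adjacent sites had been seen and entered no verdict.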
